A study of Mus musculus with 2 samples.

How the data were processed

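RNA abundance was measured in 2 clones of E14tg2a, a mouse embryonic stem cell line. The shDAB2 clone was stably transfected with a plasmid encoding a short hairpin RNA against Dab2, and the vector clone with the control plasmid. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum and 1000 U/ml of leukaemia inhibitory factor (LIF), and biotinylated cRNA was prepared from 10 µg of total RNA. Each clone was hybridised to 1 Affymetrix mouse 430A array, so the groups hold 1 sample each. The groups were taken from the sample titles.

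The deposited table holds 1 log2 expression value per probe set and array. Per the submitters' processing notes it was made with RMA, a method that subtracts background, quantile-normalizes the arrays and summarises the probes of each probe set. The RMA version, the probe set definitions and any further arrays normalized together with these are not given in the sources used here. The log base is not stated either: log2 was taken because RMA writes log2 values and because natural logs of this size would exceed the range of an array scanner. Values ran from 5.67 to 12.81 in the shDAB2 clone and from 5.65 to 12.86 in the vector clone. Sorted values of the 2 arrays differed by at most 0.07, so the distributions were close to but not exactly equal. RMA is known to shrink differences of dim probe sets, so folds near the lower end of the range are understated. The table gives no detection calls and holds 0 control probe sets (prefix AFFX), so the 3' to 5' RNA quality check and the spiked controls that had been planned were not computed.

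Probe sets were named from the platform annotation supplied with the series. Of 22626 probe sets, 20380 had 1 gene, 691 had several and 1555 were unnamed here; only those with 1 gene were used. The gene IDs of 20351 of them matched the mouse RefSeq gene table of GRCm38.p6, which changed 0 symbols and gave each gene's chromosome and the length it spans. No coordinates were used. The 20380 probe sets covered 12393 genes. A gene with several probe sets (4956 genes) took the probe set with the highest mean over both arrays. A gene counted as above the floor when the higher of its 2 values reached 6.62, the median of all probe-set values; 7269 genes did.

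The measure was the log2 value of the shDAB2 clone minus that of the vector clone. With 1 array per group no test across samples exists, so no p-value is given, and differences are described by size (at least 2-fold, a log2 difference of 1). The number of arrays limits the precision: the spread between cultures or between clones of 1 plasmid cannot be estimated. The only repeat measurement is between probe sets of 1 gene. Over 2502 genes with 2 probe sets above the floor, the 2 differences had a Pearson correlation of 0.78 across genes (genes are not independent replicates) and the SD for 1 probe set was 0.11. This SD covers probe noise and transcript variants only.

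A total of 29 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For each list with at least 5 genes above the floor, the median difference was set against 10000 random lists of the same size matched on mean expression in 10 bins, drawn from the genes above the floor. A list is called outside when its median lay under the 2.5th or over the 97.5th percentile. This describes the 2 arrays. It is not a p-value, because genes of 1 list vary together. Of lists of genes drawn at random, 5% fall outside by chance, and lists of genes that vary together can do so more often. Chromosomes were treated the same way. Named genes are Dab2, the 12 genes with the largest positive and the 12 with the largest negative difference, up to 4 genes with the largest absolute difference from each list, and Pou5f1, Sox2, Nanog, Gata4, Gata6, T, Actb and Gapdh; any other gene is said to have been chosen after its value was seen. No probe set named only for T or only for Gapdh was at hand, so neither is reported.

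The procedure was tested on simulated data for the comparison of the shDAB2 clone with the vector clone, with 7269 genes, 200 changed genes per run, 10 runs and noise with an SD of 0.16. Changes of 1.5 on the log2 scale passed the 2-fold limit in 99.7% of genes and changes of 2.0 in 100.0%. With noise this small, changes so far past the limit were bound to be recovered. Smaller changes near the limit, where most of the real 2-fold differences lay, were not simulated. Random lists without a shift fell outside in 4.4% of cases, and lists shifted by 0.3 were found above in 99.3%. The simulated noise was drawn independently for each gene, with an SD below the 0.22 of the real differences. The simulation thus covers independent genes only and cannot say how often lists of genes that vary together fall outside. The alternatives were cyclic loess (limma 3.58.1 in R 4.3.3), centring on the median, the mean of all probe sets of a gene, removal of probe sets whose IDs end in _s_at, _x_at or _a_at (they can match several transcripts), other floors and fold limits, list means, unmatched random lists and lists without shared members. Removal of a trend with gene span and signal level was added after the data were seen. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.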

Results

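The study compared the transcriptome of mouse embryonic stem cells carrying a short hairpin RNA against Dab2 with that of cells carrying the empty plasmid. Dab2 encodes Disabled-2, an adaptor protein of clathrin-mediated endocytosis that also binds signalling receptors. The question was which transcripts differ when Dab2 is targeted. One clone of each kind was profiled on 1 array (shDAB2 clone 4 and vector clone 9), in medium with LIF, the cytokine that holds these cells in the undifferentiated state. The 2 arrays correlated at r = 0.99 over 22626 probe sets, and the log2 difference had an SD of 0.22 over the 7269 genes above the floor. All values below are single measurements without replicates. They compare these 2 arrays, and a difference can belong to the clone or the culture as well as to the hairpin.

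Dab2 itself was dim on both arrays. Its brightest probe set read 6.33 in the shDAB2 clone and 6.64 in the vector clone, a log2 difference of -0.31 or 1.24-fold lower, against an SD of 0.10 for the differences of probe sets of similar signal. That mean signal exceeded only 41.2% of the probe sets on the arrays. The other probe sets of Dab2 lay below the floor and differed less, by -0.05 and -0.01. The direction is that of the label, but the size rests on 1 of the 3 probe sets, and Dab2 signal near the dim end of the arrays limits the fold that can be measured.

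Few genes differed by 2-fold. In the shDAB2 clone 2 genes were at least 2-fold higher and 13 at least 2-fold lower; at 1.5-fold the counts were 42 and 118. The highest were Upp1 (uridine phosphorylase, 3.07-fold higher), Gpx2 (a glutathione peroxidase, 2.28-fold) and Cbr3 (a carbonyl reductase, 1.93-fold). Next came Selenoh (1.83-fold), Gpx1 (1.82-fold), the neurofilament gene Nefl (1.81-fold), Rangrf (1.76-fold), Ost4 (1.76-fold), Calcoco2 (1.74-fold), the transcription factor gene Otx2 (1.70-fold), Mrpl34 (1.69-fold) and Ifitm3 (1.69-fold). Lowest was Asns, asparagine synthetase, which was 3.54-fold lower in the shDAB2 clone. It was followed by Atf4 (2.59-fold lower), Sars (2.56-fold), Psat1 (2.52-fold), the keratin gene Krt18 (2.49-fold), the growth factor gene Igf2 (2.39-fold), Klf5 (2.38-fold), Acta1 (2.29-fold), Anxa3 (2.17-fold), Cars (2.05-fold), Mthfd2 (2.05-fold) and Ahnak (2.04-fold). The thirteenth gene was the X-linked homeobox gene Rhox5 (2.02-fold lower), named here after its value was seen. Of the 15 genes, 6 had a second probe set above the floor: the sign was the same in 6 of 6, and 2 of them passed 2-fold there as well. Klf5 was the least even, at -1.25 on its brightest probe set and -0.33 on the next. At 1.5-fold, 73 of 73 genes with a second probe set had the same sign on it, and 31 of them reached 1.5-fold there.

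**Figure D1:**
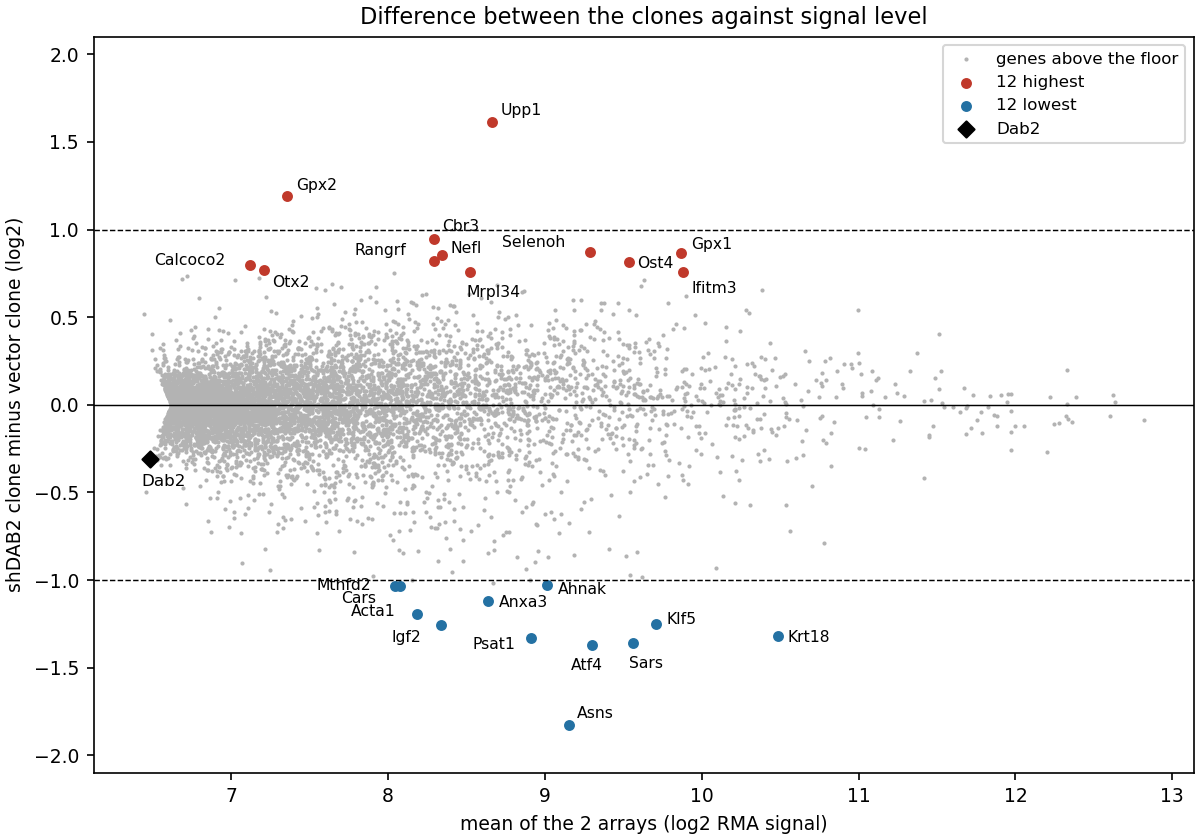
Log2 difference between the shDAB2 clone and the vector clone (y axis) against the mean log2 RMA signal of both arrays (x axis), 1 point per gene above the floor, with no error bars because each clone has 1 array. Dashed lines mark 2-fold; 13 genes lie at or below the lower line and 2 at or above the upper one, while Dab2 (diamond) lies at -0.31 near the dim end.

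Genes of the amino acid stress response were lower in the shDAB2 clone almost throughout. This list holds Atf4, the transcription factor that responds to amino acid shortage, and genes it is known to induce. Of its 23 genes above the floor 22 were lower and 1 higher, 13 of them at least 1.5-fold lower and 6 at least 2-fold. The median was -0.65, equal to 1.57-fold lower, where matched random lists ran from -0.08 to 0.10 over their central 95%. Asns read 10.07 in the vector clone and 8.24 in the shDAB2 clone, with -1.82 on the brightest and -1.81 on the second probe set. Sars, the seryl-tRNA synthetase gene, differed by -1.36 and -1.32 on its probe sets. Psat1, of serine synthesis, differed by -1.33 and -0.83, and Atf4 by -1.37 and -0.59. The list thus supplied 6 of the 13 genes at least 2-fold lower.

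**Figure D2:**
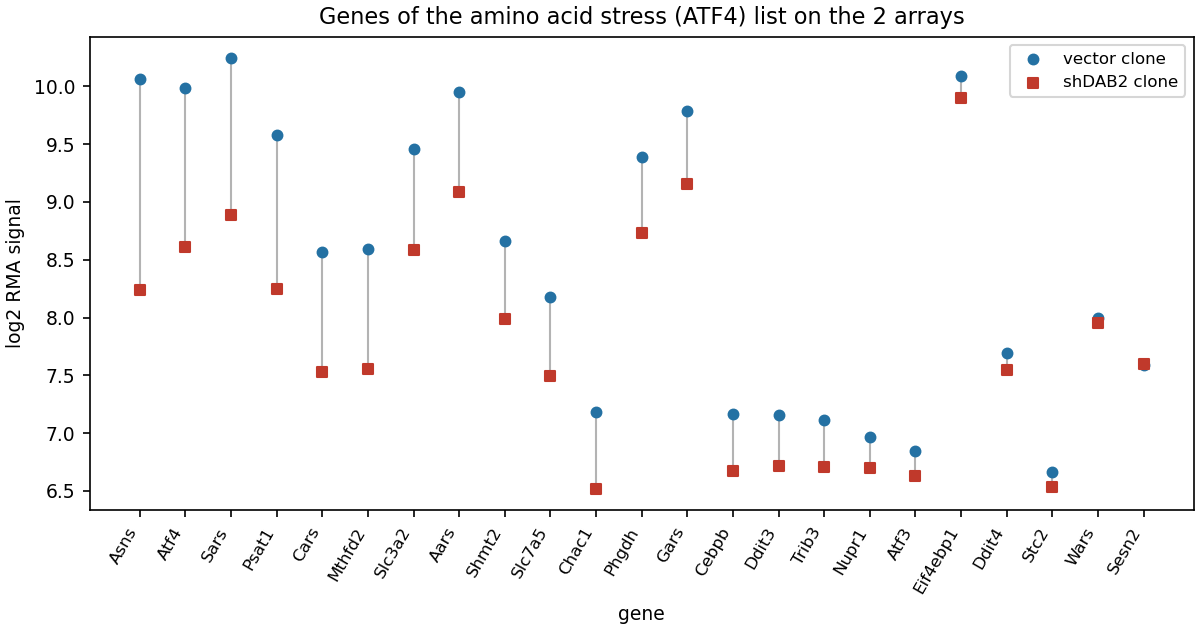
Log2 RMA signal (y axis) of each of the 23 genes of the amino acid stress (ATF4) list above the floor (x axis, ordered by difference) in the vector clone (circles) and the shDAB2 clone (squares), 1 array each. The square lies below the circle for 22 genes, by most for Asns with a difference of -1.82, and slightly above it for 1 gene.

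Protein folding genes of the endoplasmic reticulum differed the other way. Of 17 ER chaperone genes above the floor 15 were higher and 2 lower, with a median of 0.27 against -0.10 to 0.11 for random lists. Hspa5, the main ER chaperone BiP, was 1.57-fold higher, Creld2 1.53-fold, Calr (calreticulin) 1.45-fold and Manf 1.45-fold. The cytosolic heat shock list had a median of 0.14 with 8 of 13 genes higher, and lay inside its random range. Its largest differences were Serpinh1, a collagen chaperone of the ER, at -0.83, and Ahsa1 at 0.54.

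The core pluripotency genes showed little difference. Pou5f1, which encodes OCT4, differed by 0.10, Sox2 by -0.17 and Nanog by -0.02. The list's median of 0.10 over 16 genes lay inside the random range of -0.11 to 0.15; its largest members were the DNA methyltransferase gene Dnmt3b (0.40), Dppa4 (0.39), Dnmt3l (-0.32) and Gdf3 (0.30). The naive pluripotency list was mixed, with 7 genes higher, 8 lower and a median of -0.04, inside its random range; without members of other lists the median was -0.18, below the range. Within it the Krüppel-like factor genes Klf5 and Klf2 differed by -1.25 (-0.33 on the second probe set of Klf5) and -0.54. Klf4 of the same family, named after its value was seen, was 0.26 higher. Tfcp2l1 differed by -0.65, while Fgf4 was 0.61 higher. The primed epiblast list was higher, with 8 of 10 genes higher and a median of 0.24 against -0.10 to 0.11. Otx2 led it at 0.77, followed by the DNA methyltransferase gene Dnmt3a at 0.69 (0.67 on its second probe set). Sox4 stood at 0.43, but at only 0.06 on its second probe set. Cdh2 (N-cadherin) stood at 0.41, with a vector clone value of 6.47, below the floor. Among members named after their values were seen, Fgf5 was only 0.10 higher, while Sox11 (-0.05) and Tead2 (-0.25) were lower.

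Keratin genes and most matrix genes among the extraembryonic markers above the floor were lower in the shDAB2 clone. Lineage regulators were mostly too dim to compare. The trophectoderm list had 7 of 7 genes lower and a median of -0.72 against -0.18 to 0.18, carried by the simple epithelial keratin genes Krt18 (-1.32), Krt19 (-0.90), Krt7 (-0.82) and Krt8 (-0.72). Keratin genes have processed pseudogenes that probes can also match, so their values are less certain. The remaining genes above the floor were Tfap2c (-0.47, named after its value was seen), Id2 (-0.28) and Hand1 (-0.02). The other 8 measured trophectoderm genes lay below the floor and differed by -0.14 to 0.11, among them the regulators Cdx2 (-0.03), Eomes (0.11) and Elf5 (0.07), named after their values were seen. The primitive endoderm list had 9 of 13 genes lower and a median of -0.23 against -0.11 to 0.11. The largest differences included genes of matrix proteins or their chaperone: Serpinh1 (-0.83), Sparc (-0.40) and Col4a2 (-0.36), with Cited1 at -0.38. The matrix genes Lama1 (0.13) and Nid1 (0.02), named after their values were seen, were higher. The lineage regulators Gata4 and Gata6 lay below the floor on both arrays and differed by -0.13 and 0.02. With no floor the trophectoderm median was only -0.09, still below its random range, and the primitive endoderm median was 0.004, inside its range.

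Markers of embryonic germ layers and other cell types were mostly dim. Only 4 of 24 measured mesendoderm and mesoderm genes passed the floor, too few for a random range, with a median of -0.08. Among these Bmp4 differed by -0.53, Gata2 by -0.13, Nkx2-5 by 0.08 and Hand1 by -0.02. In the neuroectoderm list 3 of 5 genes were higher, with a median of 0.14 inside the random range and a mean of 0.22 above it; Nefl stood at 0.86, Nefm at 0.28, Tubb3 at 0.14 and Stmn2 at -0.09. The blood and endothelium list had 3 genes above the floor and a median of 0.06, with Runx1 at 0.09 (-0.03 as the mean of its probe sets), Gfi1b at 0.06 and Itga2b at 0.05. The germ cell list had a median of -0.26 over 5 genes, outside its range of -0.16 to 0.15, with Stag3 at -0.56, Prdm1 at -0.31, Sycp3 at -0.26 and Dppa3 at 0.39; its call was lost with no floor or with the list mean. The fibroblast list had a median of -0.19 over 9 genes, 7 of them lower, against -0.14 to 0.14; the call was lost without members of other lists. The actin-binding gene Tagln led it at -0.98, then fibronectin (Fn1) at -0.59 and Thbs1 at -0.40. Vimentin (Vim) was 0.31 higher on its brightest probe set and 0.10 higher on the next.

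Genes of epithelial adhesion and of the extracellular matrix were lower as groups. The epithelial list had 16 of 17 genes lower and a median of -0.31 against -0.12 to 0.14; apart from the keratin genes the claudin gene Cldn4 stood out at -0.77. The matrix and integrins list had 18 of 22 genes lower and a median of -0.28 against -0.09 to 0.10. Its integrin genes Itga3 and Itga6 differed by -0.57 and -0.40 and, on second probe sets, by -0.73 each. Genes of clathrin endocytosis, the process in which the Dab2 protein acts, were lower by a small amount: 17 of 21 genes, with a median of -0.12 against -0.08 to 0.09. The megalin gene Lrp2, a cargo receptor that Dab2 binds, differed by -0.33, clathrin heavy chain (Cltc) by -0.25 and Hip1 by -0.24, while the transferrin receptor gene Tfrc was 0.41 higher. The endocytosis call was lost under 4 of the 10 alternatives, among them the list mean of -0.09.

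**Figure D3:**
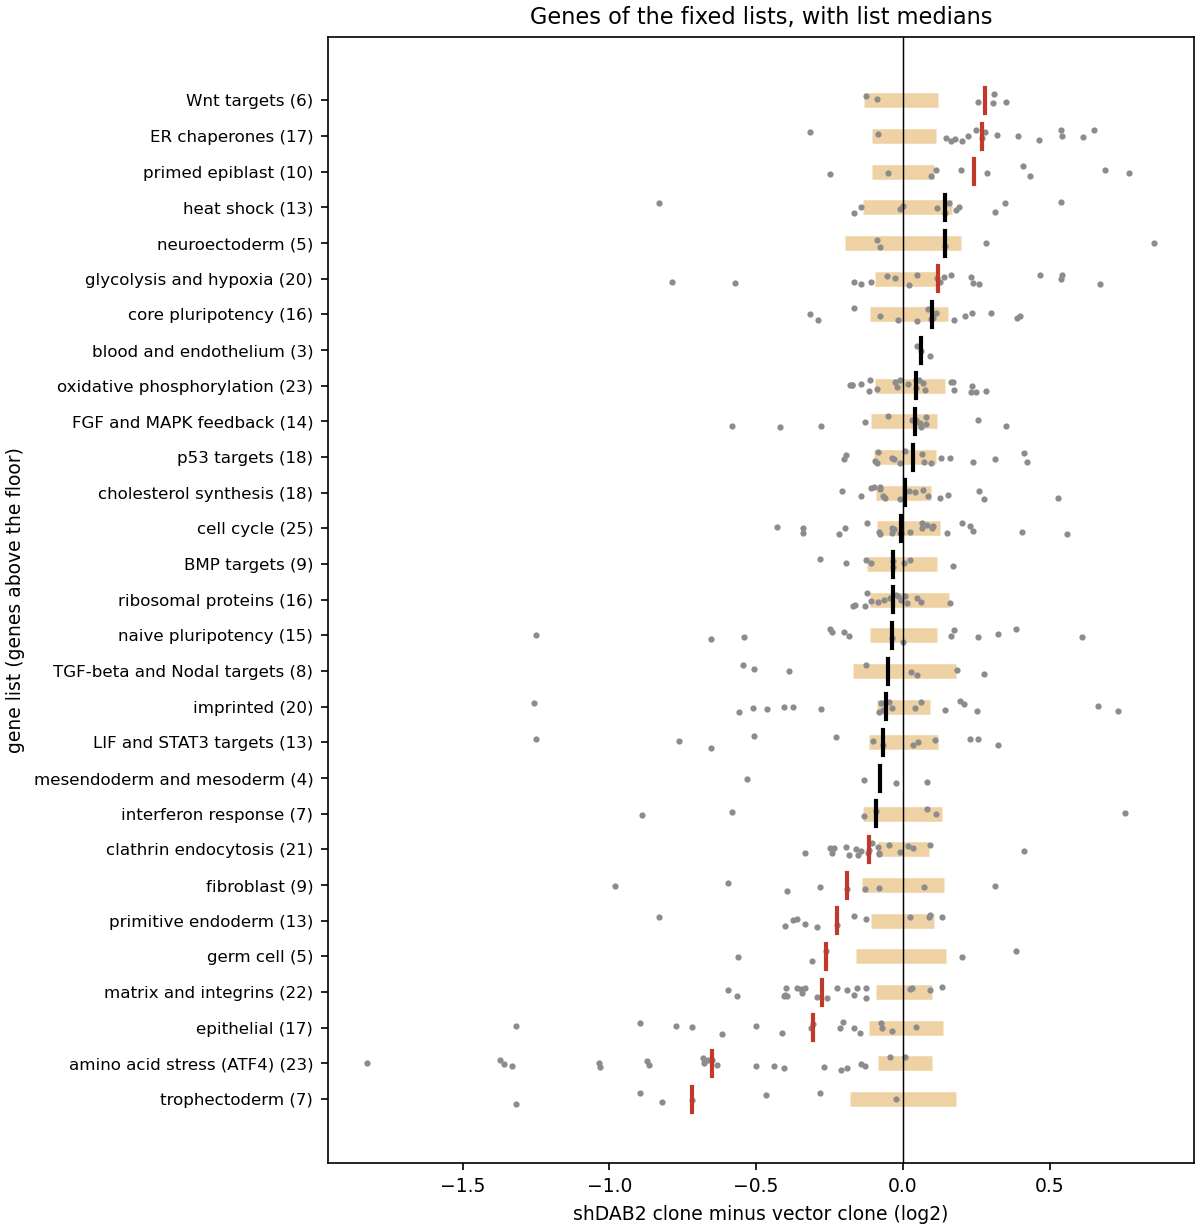
Log2 difference between the shDAB2 clone and the vector clone (x axis) for the genes above the floor of each of the 29 lists (y axis, number of genes in brackets), 1 grey point per gene. Vertical ticks are list medians (red where outside the central 95% of 10000 matched random lists, shown as bands, black otherwise); the trophectoderm and ATF4 lists lie lowest at -0.72 and -0.65.

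Among signalling readouts, the Wnt target list was higher, with 4 of 6 genes higher and a median of 0.28 against -0.13 to 0.12. The higher ones were the cyclin D genes Ccnd1 (0.35) and Ccnd2 (0.31), Notum (0.31) and Myc (0.25), of which Ccnd1 and Myc also stand in the MAPK list. Axin2 (-0.09) and Sp5 (-0.12), named after their values were seen, were lower. The call was lost with no floor, and 4 of the 10 alternatives left under 5 genes, so it could not be made there. The TGF-beta and Nodal target list had a median of -0.05, with Ccn1 at -0.54, Junb at -0.51, Lefty1 at -0.39 and Nodal at 0.28. The BMP target list had a median of -0.03 and its largest differences were Id2 (-0.28), Id1 (-0.19), Bambi (0.17) and Smad7 (-0.13). In the FGF and MAPK feedback list the median was 0.04 and the mean -0.03, with Phlda1 at -0.58, Spry1 at -0.42 and Spred1 at -0.28. The LIF and STAT3 target list had a median of -0.07 and a mean of -0.20, the mean lying below its random range, with the kinase gene Pim1 at -0.76 beside Klf5 and Tfcp2l1. The medians of these last 4 lists lay inside their random ranges.

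Growth and energy genes differed little as groups. The cell cycle list had a median of -0.01 and a mean of 0.01 over 25 genes, although cyclin E1 (Ccne1) was 0.56 and Pcna 0.40 higher while Ccnb2 and Mki67 differed by -0.43 and -0.34. The ribosomal protein list had a median of -0.03 over 16 genes. Its largest members were Rpl10a (-0.17), Rps4x (-0.16, but 0.05 on its second probe set), Rps6 (0.16) and Rps14 (-0.13). For oxidative phosphorylation the median was 0.04 over 23 genes, with Cycs at 0.28, Cox7a2 at 0.25, Sdhd at 0.24 and Atp5a1 at 0.23. The cholesterol synthesis list had a median of 0.01 over 18 genes. Its largest differences were Idi1 at 0.53, Hmgcs1 at 0.28, Ebp at 0.26 and Srebf2 at -0.21. The second probe set of Hmgcs1 gave -0.21, so its direction is uncertain. These 4 lists lay inside their random ranges. The glycolysis and hypoxia list lay just above its range, with a median of 0.12 against -0.10 to 0.11 and 13 of 20 genes higher; the call was lost under 4 of the 10 alternatives. It split between the glucose transporter genes Slc2a3 (-0.79) and Slc2a1 (-0.57) on one side and Bnip3 (0.67) and Ldha (0.54) on the other. Of the 20 genes, Nlk (-0.17), named after its value was seen, is not in the fixed list. It entered through an older symbol shared with a listed gene, and the call was not rerun without it. Actb, a common reference gene, differed by -0.06.

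The remaining lists lay inside their random ranges. The interferon response list, which a hairpin RNA can induce, had 7 genes above the floor and a median of -0.09. Its members went apart, with Ifitm3 at 0.76, B2m at -0.89, Bst2 at -0.58 and Tap1 at -0.13. The p53 target list had a median of 0.04 over 18 genes, with Ei24 at 0.42, Pmaip1 at 0.41, Ccng1 at 0.31 and Btg2 at 0.24. The imprinted list had a median of -0.06 over 20 genes. Within it Igf2 (-1.26) and Gnas (-0.56) were lower and the neighbouring noncoding RNA genes Rian (0.73) and Meg3 (0.67) higher; the second probe sets of Rian and Meg3 gave 0.67 and 0.78.

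Of 27 lists with enough genes, 12 lay outside the central 95% of random lists, 8 lower and 4 higher. For lists of genes drawn at random 1.35 would. Genes of 1 list vary together, so real lists can fall outside more often than that. Lists share members: 5 of the 7 trophectoderm and 10 of the 13 primitive endoderm genes stand in another list. By chromosome, a check on gains or losses in these clones, 7 of 20 medians lay outside their random range. For genes drawn at random 1.00 would. All were small in size. The largest were chromosome 12 at 0.06 over 236 genes and chromosome 8 at 0.05 over 404 genes. Their random ranges were -0.02 to 0.03 and -0.02 to 0.02, and both lay at percentile 100.0. Both medians were positive, the direction of a gain and not of a loss. They lay far below the 1.5-fold that 1 extra copy in every cell would give if expression followed copy number. A gain in a part of the cells or of a part of these chromosomes stays open. The lowest was the X chromosome at -0.03 over 210 genes. Of 8 Y-linked genes 1 was above the floor, and their median was -0.02.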

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

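Removal of the span and signal trend was chosen after the data were seen. The counts kept their size, within 1.5 times, under every alternative except these. Taking the mean of all probe sets of a gene left 8 genes at least 2-fold lower, 7 of them among the 13, and a Dab2 difference of -0.12; the other Dab2 probe sets gave -0.051 and -0.011. The cause was not tested beyond the dim signal of those probe sets. By construction a 1.5-fold limit gave 42 higher and 118 lower genes, and a 3-fold limit 1 and 1. Otherwise 2 genes were 2-fold higher throughout and the lower count ran from 10 (without _s_at, _x_at and _a_at probe sets) to 19 (counting probe sets), with 17 after cyclic loess. The number of lists outside ran from 8 to 14 and that of chromosomes from 5 to 8. The ER chaperone, ATF4, epithelial, matrix and primed epiblast lists lay outside under all 10 alternatives, and the trophectoderm list under all 8 that left it 5 genes. The primitive endoderm median turned to 0.004 with no floor, which adds genes that lie near the lower end of the range; the cause was not tested. The fibroblast call was lost without shared members, and the heat shock list lay outside under 3 alternatives. The LIF and neuroectoderm lists lay outside with the list mean, the naive list without shared members and the core pluripotency list against unmatched random lists. Medians near 0 (cell cycle, cholesterol, p53, ribosomal, TGF-beta and interferon lists) changed sign with the choice of probe sets, floor or members. For the named genes 447 values moved by less than the probe-set SD of 0.11 and 31 by more. Centring and cyclic loess left all 125 genes within that SD, but centring shifts every gene by the same small amount and could not do otherwise. The mean of all probe sets moved 24 genes and kept 101, and a gene with 1 probe set cannot move there. Without _s_at, _x_at and _a_at probe sets 7 moved and 96 did not. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. The 3' to 5' check and its median-centred version were not run, for want of control probe sets. Dim signal limits Dab2 and most lineage markers.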

Other observations

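The gene sets and the tests in this part were chosen after the differences had been seen; the results of the second probe set and span trend tests were not yet known when those tests were chosen. Cytosolic tRNA synthetase genes, whose enzymes load amino acids onto tRNAs, differed widely. Of 18 measured, 14 were lower and 8 at least 1.5-fold lower in the shDAB2 clone. Nars (-0.97), Lars (-0.84) and Yars (-0.72), known ATF4 targets outside the fixed list, were among the lowest. Other known targets differed less, with Eprs at -0.23 and Wars at -0.04, close to or above Vars (-0.21) and Qars (-0.21), which are not counted as targets. Hars (0.17), Kars (0.10), Rars (0.07) and Farsa (0.58) were higher. The 8 mitochondrial synthetase genes had a median of -0.06, inside the random range of -0.12 to 0.10.

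Genes of the actin cytoskeleton and the annexins were lower in 36 of 38 cases, 13 of them at least 1.5-fold, with a median of -0.36 against -0.07 to 0.10. Beside Acta1 and Tagln these included Cald1 (-0.87), Pdlim7 (-0.83), Cnn2 (-0.82), Anxa1 (-0.78), Tagln2 (-0.74), Myh9 (-0.69) and Flna (-0.68). The abundant actin genes Actb and Actg1 differed by only -0.06 and -0.11. Selenoprotein genes supplied 3 of the 12 highest genes and 4 of the 42 at least 1.5-fold higher: Gpx2 (1.19), Selenoh (0.87), Gpx1 (0.87) and Selenop (0.61). The whole set of 19 had a median of 0.08, inside its range of -0.09 to 0.10, with Gpx4 at -0.08 and Selenof at -0.08.

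For the lower ATF4 list, noise of single probe sets is argued against by the second probe sets of 14 of its genes, 14 of which were lower, with a median of -0.54 against -0.12 to 0.10. A trend with gene span or signal level left the median at -0.64 once removed, although the trend was present (Spearman rho -0.14 across genes, 0.01 after removal). Less folding stress in the ER was taken to lower the ER chaperones, which were instead higher, with a median of 0.27. Of the 17 genes 15 were higher, while Herpud1 (-0.32) and Edem1 (-0.08), named after their values were seen, were lower. That median was already known when the prediction was written, so it is not an independent test and does not exclude this explanation. Lower ATF4 activity is a candidate explanation that stays open: the 6 synthetases taken as targets outside the list differed from 15 others by -0.74 in the median, but they were set apart after their values had been seen, and Wars, a target inside the list, lay at -0.04. Clone or culture rather than DAB2 stays open, such as a difference in amino acid supply at harvest, because there is 1 array per group.

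The lower keratin and actin-binding genes could reflect cell shape, adhesion or a smaller share of differentiated cells. A trend with gene span or signal level is argued against for the fixed lists. With that trend removed the medians were -0.73 for the trophectoderm list and -0.24 for the epithelial list, both below their random ranges. The actin and annexin set stood at -0.34, also below its range. That set was chosen after its values were seen, so its place adds no support. Fewer differentiated cells of every kind cannot be told apart from other causes, since the neuroectoderm list rested on 5 genes, with a median of 0.14 inside its range and a mean of 0.22, raised by Nefl, above it. Fewer fibroblasts stay open too: the fibroblast list was lower (median -0.19, inside its range without shared members), but the collagen genes Col1a1, Col1a2 and Col3a1 were below the floor in both clones, with a median difference of -0.022 that decides nothing. The hairpin itself, as the design names it, remains among the open explanations and was not tested.

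For the 4 selenoprotein genes at least 1.5-fold higher, gene span was examined because a shorter span went with higher values: the tenth of genes with the shortest span had a median of 0.03 and the tenth with the longest -0.04. Removing that trend left the median of Gpx1, Gpx2, Selenoh and Selenop at 0.82. The trend was small beside differences of this size. The 4 genes were picked for being high, so this outcome was fixed in advance and adds no support to the pattern. More selenium in the shDAB2 culture is a candidate explanation, since Gpx1 and Selenoh transcripts are known to depend on selenium supply. The 2 further selenium-sensitive genes, Selenow (0.27) and Msrb1 (0.30), lay on average 0.29 above the median of the 15 other selenoproteins. The limit of 0.32 (3 probe-set SDs) was set for each gene on its own. Neither gene passed it, so the comparison decides nothing.

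Among probe sets unnamed here or of several genes, 1 passed 2-fold, an unnamed one at -1.13.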
